A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

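The measurements were poly(A)+ directional RNA-seq libraries from mother cells of Saccharomyces cerevisiae diploids of the mother enrichment programme, in 3 deposited tables. Each value was a log2 value scaled by the authors, and not a count. The low values of every library fell on whole read numbers when the lowest value was set to a count of 0 entered as 0.9, within a tolerance of 0.02. Reads per feature were recovered in this way for depth, for reads of single genes and for shares of reads. The log2 values themselves were used for the tests of the comparisons; reads were used for voom and for binomial intervals and tests of read numbers. The design written beforehand had allowed for log2 values or for counts; the steps for log2 values were the ones that applied. The 3 tables were normalised separately, so tests were made only within a table.

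According to the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6 and aligned with HISAT2 2.1.0 to build R64. The program that counted reads, its strand setting and the method behind the scaling are not given in the sources used here. Spacers of the ribosomal DNA were held on both strands in the mus81 table, antisense only in the hst3 hst4 table and not at all in the translocation table. Counting by strand was assumed for all 3 tables. Each table held 6664 genes, of which 5988 had an identifier in the reference annotation and 5980 had identical coordinates there. Reads of near-identical copies cannot be told apart with certainty: 404 genes shared exact stretches of 50 bases with another gene over 30 percent of their length, or overlapped a gene on the same strand, and are marked * where named.

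Groups, comparisons, gene lists and the main alternatives were chosen before the data were examined. Features above the floor of their library in at least 2 libraries were tested: 6669 in the mus81 table, 6613 in the hst3 hst4 table and 6651 in the translocation table. Linear models were fitted with limma 3.58.1 (lmFit, then eBayes with a trend of variance on level). The mus81 table had 12 libraries in 6 groups and 6 residual degrees of freedom. The hst3 hst4 table had 6 libraries in 4 groups and 2 residual degrees of freedom; its lone wild-type libraries were assumed to vary like the hst3 hst4 pairs. The translocation table had 6 libraries, 1 per strain and age, and was fitted with strain and age as additive terms, which left 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. P-values of the comparisons, including those beside 2 libraries per group, came from limma.

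Gene lists were tested with camera from limma at the preset correlation of 0.01 between genes, for lists of at least 3 members, with adjustment over the lists of a comparison. The test was repeated with the correlation estimated from the residuals. The 32 lists were: cytosolic ribosomal proteins, ribosome biogenesis, general stress response, heat shock chaperones, iron regulon, gluconeogenesis and glyoxylate, respiratory chain and TCA, glycolysis, hexose transporters, galactose use, phosphate regulon, amino acid biosynthesis, ergosterol biosynthesis, cell wall stress, DNA damage response, histones, G1/S genes, G2/M genes, daughter cell markers, haploid-specific genes, meiosis and sporulation, proteasome, silencing and rDNA stability, strain markers, 2-micron plasmid, rDNA locus coding, subtelomeric, mitochondrially encoded, chromosome XII right of the rDNA, chromosome XII left of the rDNA, chromosome V left arm and chromosome V right arm. Members came from general knowledge of yeast genes or from position, and were written down without the values. Subtelomeric genes had their midpoint within 25 kb of a chromosome end.

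Where a group had 1 library, differences were given without p-values. The median of a list was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. Named genes were the 10 largest rises and the 10 largest falls among called genes in the 4 main comparisons, and 5 of each in the other comparisons. Such a gene had a mean level above the 25th percentile, and its libraries did not overlap between the groups. Up to 4 members with the largest changes were eligible per list. Deleted genes, strain markers and the spacer and plasmid features were always eligible. Genes named outside this rule are said to be chosen after their values were seen.

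Alternatives replaced the deposited scaling by quantile normalization or by median centring, removed the filter, or left out the lowest genes by level (those under the 25th percentile), and removed the variance trend. Further ones added replicate numbers as a block, kept only the groups compared, or left out 1 library at a time. Added after the data had been seen were limma voom on the recovered reads, a crossed pairing of replicate numbers, and leaving out translocation libraries. Intervals of read ratios were exact binomial intervals and those of read shares were Wilson intervals, both at 95 percent; they cover counting error only. The check for gene length divided genes into 20 bins of length and was also chosen after the data had been seen.

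The steps were tested on simulated data in which 200 features were changed by a log2 of 1.5, in 10 tables per comparison. The share of changed features recovered was 99.1 percent for wild type at 48 h against log, 99.3 percent for mus81 against wild type at 48 h, 89.8 percent for hst3 hst4 aged against log and 85.4 percent for translocation strain against control. The share of false calls was 5.17, 4.84, 5.77 and 4.36 percent in the same order. The simulated spread was drawn from the fitted model with independent errors, so false shares near the threshold follow from the model. They do not test whether lone libraries vary like the pairs, nor strain-by-age differences in the spread. Versions were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.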

Results

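RNA from purified mother cells of diploid budding yeast was measured by poly(A)+ RNA-seq in log phase and after ageing for 24 h or 48 h, in 24 libraries held in 3 tables. The mus81 table had 12 libraries: wild type and mus81 mutant in log phase, at 24 h and at 48 h, with 2 libraries per group. The hst3 hst4 table had 6 libraries: the double mutant in log phase and aged (n = 2 each), and wild type in log phase and aged (n = 1 each). The translocation table had 6 libraries: a control strain and a strain whose chromosome XII part to the right of the ribosomal DNA (rDNA) was moved to chromosome V, each in log phase, at 24 h and at 48 h (n = 1 each). Recovered reads per library ranged from 1656535 in wild-type 24 h replicate 2 to 11330955 in mus81 log replicate 1. The hst3 hst4 libraries had 3964134 to 8557984 reads and the translocation libraries 1798756 to 5719392.

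Nothing in the labels states that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The correlation between replicates of a group in the tables ranged from 0.967 (wild type at 24 h) to 0.992. Tests were made within a table with limma, and adjusted p refers to the Benjamini-Hochberg method. Levels set side by side across tables come from tables that were normalised separately. In the hst3 hst4 table the titles and the age labels differ (48 h and 24 h), so its old cells are called aged. Its genotype label reads wild type for all 6 libraries, and the titles were followed because HST3 and HST4 reads separated the libraries in the same way.

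The deleted genes were examined first. MUS81 (chromosome IV, 1246084 to 1247982) had 117, 107, 150, 39, 149 and 161 reads in the 6 wild-type libraries and 10, 0, 10, 2, 2 and 10 in the 6 mus81 libraries. Wild type exceeded mus81 26.9-fold (interval 14.3 to 56.8) in log phase, 20.4-fold (11.4 to 40.1) at 24 h and 31.8-fold (18 to 62.3) at 48 h. It was 16.9-fold without mus81 log replicate 2, with 0 reads left without mus81 log replicate 1, 55.1-fold and 13.4-fold without mus81 24 h replicate 1 and replicate 2, and 17.9-fold and 101-fold without mus81 48 h replicate 1 and replicate 2. HST3 (chromosome XV, 378219 to 379562) was 67.2-fold (28.5 to 209) lower in the hst3 hst4 strain in log phase and 41.6-fold (25.2 to 73.7) lower in aged cells. HST4 (chromosome IV, 842337 to 843449) had 0 reads in the hst3 hst4 log libraries against 90 in wild type, and 2 against 87 in aged cells. URA3 was 129-fold (59.1 to 353) higher in mus81 than in wild type in log phase, and 7.76-fold (5.78 to 10.6) and 13.6-fold (9.12 to 21) higher at 24 h and 48 h. These URA3 ratios rested on single wild-type libraries with few reads: at 24 h 2.51-fold without wild-type 24 h replicate 1 and 20.9-fold without replicate 2, and at 48 h 33.4-fold without wild-type 48 h replicate 1 and 7.59-fold without replicate 2. TRP1 was 538-fold (149 to 4440) higher in aged hst3 hst4 cells than in aged wild type. These intervals are exact binomial intervals and cover counting error only.

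Accumulation of rDNA spacer transcripts with age was examined in features the submitters named IGS1 (459797 to 460922) and IGS2 (457733 to 459675). Both strands were taken in the mus81 table. Extrachromosomal rDNA circles carry the spacers and are known to build up in mother cells. Whether these bounds hold spacer sequence alone, without neighbouring transcribed rDNA, was not checked. IGS2-1AS held 132253 reads and IGS1-2AS 2226 in the aged wild-type library of the hst3 hst4 table. In wild type the spacers took 0.0252 and 0.0248 percent of reads in the log libraries, 2.84 and 1.78 percent at 24 h, and 1.83 and 3.43 percent at 48 h. In mus81 the shares were 0.0321 and 0.0282 percent in log phase, 0.728 and 0.275 percent at 24 h, and 0.339 and 0.457 percent at 48 h. Only the antisense features were held in the hst3 hst4 table, where their share was 0.0188 percent in log wild type and 2.39 percent in aged wild type (n = 1 each). In the hst3 hst4 strain it was already 0.545 and 0.607 percent in log phase, and 1.97 and 1.86 percent in aged cells.

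Wild type was compared between 48 h and log phase to ask what changed in old mother cells, in which stress genes and a slower ribosome programme are known from earlier work on yeast ageing. The general stress genes HSP26 and HSP12 rose by log2 8.89 (SE 0.27, adjusted p = 1.11e-11) and 8.16 (SE 0.19, adjusted p = 5.54e-13; n = 2 per group). TMA10 rose by 7.83 (SE 0.20), PIR3 by 6.37 (SE 0.20) and NCA3 by 5.34 (SE 0.23). The sense spacer feature IGS1-2S rose by 7.68 (SE 0.36, adjusted p = 9.05e-10) and IGS2-1S by 5.90 (SE 0.30). Antisense, IGS2-1AS rose by 5.67 (SE 0.44) and IGS1-2AS by 4.37 (SE 0.51, adjusted p = 2.98e-06). Among the largest falls were YHB1 at −3.39 (SE 0.30), PHO11* at −3.73 (SE 0.30) and DBP2 at −2.77 (SE 0.20). In all, 2206 genes rose and 2005 fell of 6669 tested, and the median of all genes was 0.15.

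Growth lists fell in wild type at 48 h. Of 138 cytosolic ribosomal protein genes 133 fell and none rose (133 adjusted over the list alone; median −1.18, adjusted p = 5.74e-26 by camera, adjusted p = 0.168 with an estimated correlation), among them RPL3 at −2.03 and RPL9A at −1.77. All 88 ribosome biogenesis genes fell (median −1.69, adjusted p = 1.73e-29, adjusted p = 0.184 with an estimated correlation), such as NSR1 at −2.63 and LSG1 at −2.43. Glycolysis genes fell for 14 of 17 members and rose for 1 (median −1.36, adjusted p = 1.14e-05, adjusted p = 0.184 with an estimated correlation), with ENO2 at −2.48 and ADH1 at −2.26. The phosphate regulon fell for 15 of 18 members and rose for 3 (median −1.96, adjusted p = 4.8e-05, adjusted p = 0.207 with an estimated correlation). Histones fell for 10 of 11 members (median −1.29, adjusted p = 0.00011, adjusted p = 0.153 with an estimated correlation), such as HTA2 at −1.82 and HTB2 at −1.77. Daughter cell markers fell for 11 of 12 (median −1.20, adjusted p = 0.00011, adjusted p = 0.265 with an estimated correlation), with PRY3 at −2.48 and EGT2 at −1.96. The share of daughter cells may thus differ between log and aged libraries, which was not tested, so these comparisons may not measure age alone. G1/S genes fell for 16 of 30 and rose for 2 (median −0.37, adjusted p = 0.0168, adjusted p = 0.153 with an estimated correlation), such as MNN1 at −1.43. Ergosterol genes fell for 16 of 23 and rose for 2 (median −0.46, against 0.07 after quantile normalization; adjusted p = 0.001, adjusted p = 0.163 with an estimated correlation), such as ERG6 at −1.22. Amino acid biosynthesis genes rose for 13 and fell for 26 of 51 (median −0.33, against 0.10 after quantile normalization; adjusted p = 0.0168, adjusted p = 0.649 with an estimated correlation), from ARG3 at 3.23 to LYS20* at −1.80.

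Lists of stress, glucose-repressed and developmental genes rose in the same comparison. General stress response genes rose for 37 of 40 members (37 adjusted over the list alone; median 3.04, adjusted p = 1.1e-15, adjusted p = 0.153 with an estimated correlation), such as DDR2 at 7.99. Gluconeogenesis and glyoxylate genes rose for 23 of 26 and fell for 2 (median 2.79, adjusted p = 2.17e-06, adjusted p = 0.062 with an estimated correlation), with FBP1 at 7.01 and SFC1 at 6.04. Respiratory chain and TCA genes rose for 48 of 51 (median 1.19, adjusted p = 3.65e-13, adjusted p = 0.163 with an estimated correlation), with NDE2 at 5.87 and CYC7 at 4.33. Hexose transporters rose for 13 of 16 and fell for 2 (median 2.90, adjusted p = 0.00101, adjusted p = 0.0881 with an estimated correlation), such as HXT14 at 5.30. Galactose genes rose for 8 of 8 (median 1.82, adjusted p = 0.00769, adjusted p = 0.163 with an estimated correlation), such as GAL2 at 4.89. Cell wall stress genes rose for 16 of 19 and fell for 2 (median 2.00, adjusted p = 1.47e-05, adjusted p = 0.257 with an estimated correlation), with PRM5 at 3.90 and YLR194C at 3.51. DNA damage response genes rose for 15 of 25 and fell for 4 (median 0.77, adjusted p = 0.0432, adjusted p = 0.207 with an estimated correlation), such as HUG1 at 5.09. Iron regulon genes rose for 17 of 28 and fell for 3 (median 0.59, adjusted p = 0.0168, adjusted p = 0.441 with an estimated correlation), with FIT3 at 3.99 and FIT2 at 3.90.

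Haploid-specific genes rose for 28 of 34 and fell for 2 (median 1.54, adjusted p = 1.84e-05, adjusted p = 0.0881 with an estimated correlation), with FUS1 at 5.52 and FIG1 at 4.70. Meiosis and sporulation genes rose for 50 of 60 and fell for 1 (median 2.47, adjusted p = 1.74e-09, adjusted p = 0.0881 with an estimated correlation), with CDA1 at 7.29 and SPS2 at 6.58. Subtelomeric genes rose for 205 of 392 and fell for 37 (median 1.19, adjusted p = 2.17e-06, adjusted p = 0.156 with an estimated correlation), with STL1 at 5.69 and JEN1 at 5.55. The rDNA locus coding genes rose for 5 of 5 (median 2.60, adjusted p = 0.00047, adjusted p = 0.163 with an estimated correlation), with TAR1 at 4.35 and ASP3-1* at 2.62. Of 4 features of the 2-micron plasmid 3 rose (median 1.55, adjusted p = 0.0161, adjusted p = 0.254 with an estimated correlation), the largest being 2271..2816 at 2.92 (SE 0.13).

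Several lists were not called as groups in wild type at 48 h. Heat shock chaperones rose for 13 and fell for 6 of 25 (median 0.41, adjusted p = 0.0794). The proteasome list had 4 rises and 8 falls among 34 members (3 and 7 adjusted over the list alone; median −0.15, adjusted p = 0.22, against 0.31 after quantile normalization). Silencing and rDNA stability genes rose for 5 and fell for 9 of 23, with a median of 0.05 but a mean of −0.05 (adjusted p = 0.448); SIR2 fell by 1.20, FOB1 by 1.28 and NET1 by 1.40. G2/M genes rose for 5 and fell for 7 of 20 (median −0.12, adjusted p = 0.645), such as YHP1 at −1.39. Strain markers rose for 4 and fell for 2 of 12 (adjusted p = 0.842), among them UBC9 at −3.29 and TOM70 at −1.24. The mitochondrially encoded list matched 0 genes. Chromosome XII left of the rDNA rose for 82 and fell for 64 of 229 (median 0.17, adjusted p = 0.67), chromosome V left for 29 and 26 of 92 (median 0.36, adjusted p = 0.688), and chromosome V right for 69 and 72 of 236 (median 0.10, adjusted p = 0.651, with the test pointing down). Of 31 lists tested 23 were called, and none with an estimated correlation.

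**Figure D1:**
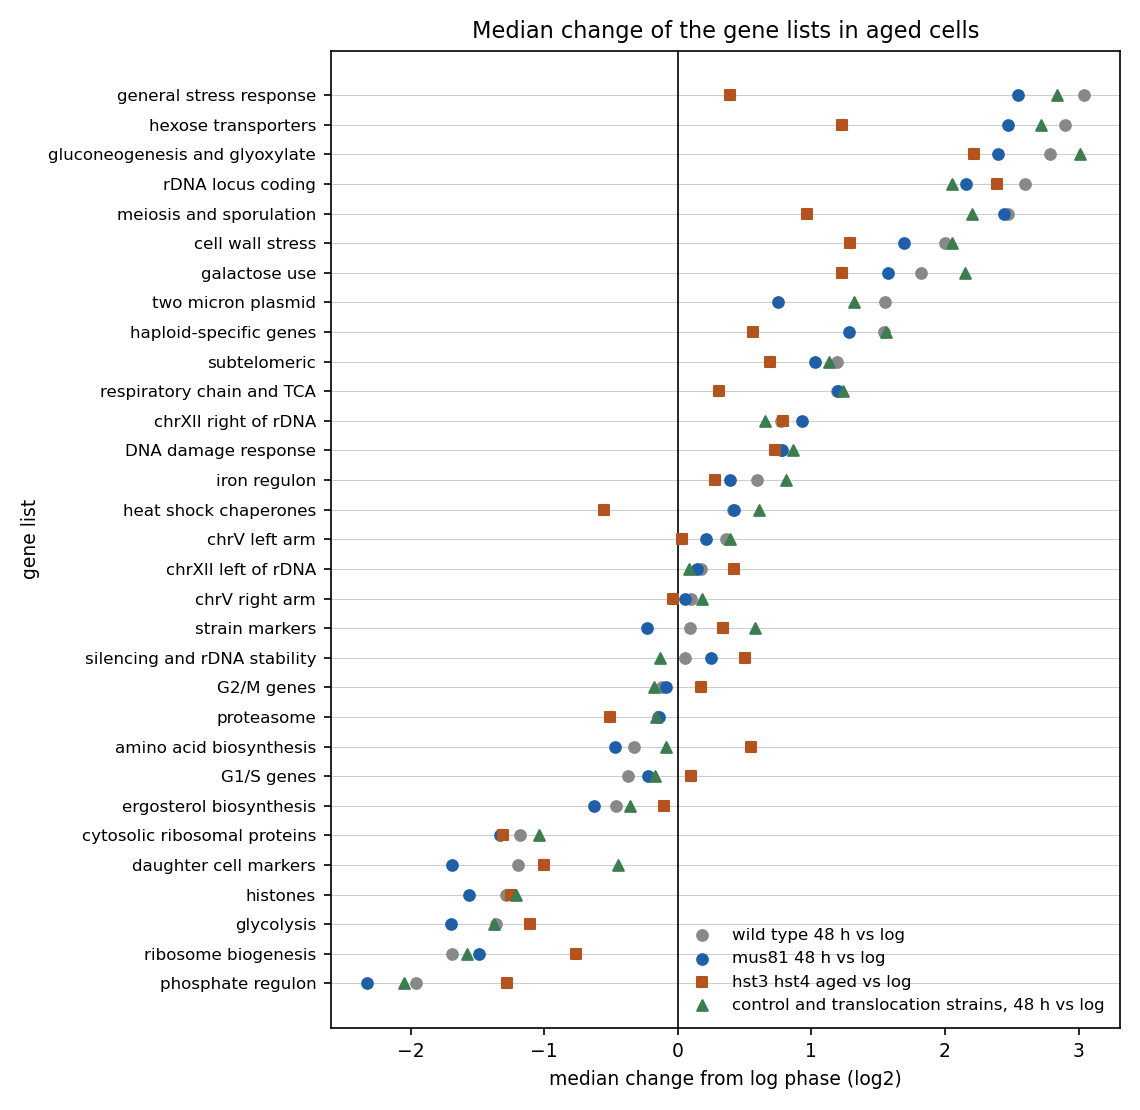
Median log2 change of each gene list in aged cells against log phase, in wild type and mus81 (n = 2 per group), hst3 hst4 (n = 2 per group), and both strains of the translocation table (n = 1 per strain and age). Tables were normalised separately, and after quantile normalization the median at 48 h turned sign for ergosterol (0.07), proteasome (0.31) and amino acid (0.10) genes in wild type. It turned likewise for proteasome (0.33) in mus81 and for amino acid (0.24) genes in the translocation table, and the test turned for ergosterol (−0.02) there and for heat shock chaperones (−0.05) in hst3 hst4.

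The spacer rise was in place by 24 h in wild type. Against log phase, IGS1-2S rose by 7.33 (SE 0.36, adjusted p = 3.52e-09), IGS2-1S by 6.29, IGS2-1AS by 5.89 and IGS1-2AS by 4.52 (n = 2 per group). HSP12 rose by 6.91, HSP26 by 6.77 and TMA10 by 6.38, while BSC1 fell by 2.19, YHB1 by 1.86 and PRY3 by 1.67. URA3 rose by 3.91 (adjusted p = 0.000627), and by 2.35 without wild-type 24 h replicate 2 (adjusted p = 0.00656). Cytosolic ribosomal proteins fell for 117 members (median −0.60, adjusted p = 1.15e-18, adjusted p = 0.27 with an estimated correlation), ribosome biogenesis fell for 88 (median −0.97, adjusted p = 4.7e-28, adjusted p = 0.241 with an estimated correlation), and general stress response rose for 36 and fell for 1 (median 1.79, adjusted p = 1.76e-16, adjusted p = 0.169 with an estimated correlation). In all 1626 genes rose and 1615 fell, and 19 of 31 lists were called, none with an estimated correlation.

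Between 24 h and 48 h the stress and growth lists moved further in wild type, and no spacer feature was called. HSP26 rose by 2.12, CTT1 by 2.00 and HXT5 by 1.69, and PHO84 fell by 1.78 and PHO89 by 2.06 (n = 2 per group). General stress response rose for 28 members (31 adjusted over the list alone; median 1.13, adjusted p = 1.6e-18, adjusted p = 0.131 with an estimated correlation), ribosome biogenesis fell for 80 (median −0.71, adjusted p = 2.38e-33, adjusted p = 0.14 with an estimated correlation), and ribosomal proteins fell for 99 (112 adjusted over the list alone; median −0.59, adjusted p = 4.65e-31, adjusted p = 0.136 with an estimated correlation). Of 31 lists 23 were called, none with an estimated correlation. IGS1-2S stood at 0.35 (SE 0.36, adjusted p = 0.536), IGS2-1S at −0.39 (SE 0.30, adjusted p = 0.395), IGS2-1AS at −0.22 (SE 0.44, adjusted p = 0.78) and IGS1-2AS at −0.16 (SE 0.51, adjusted p = 0.869). In all 604 genes rose and 848 fell. The total of 1452 fell to 672 without wild-type 24 h replicate 2 and to 283 without wild-type 48 h replicate 1.

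The mus81 strain aged with many of the same genes. At 24 h YLR042C rose by 6.93, TMA10 by 6.59 and HSP26 by 6.30, while PLB2 fell by 2.76 and YHB1 by 2.54 (n = 2 per group). At 48 h HSP26 rose by 7.55, YLR042C by 7.52 and TMA10 by 7.11, while PHO12* fell by 5.14, PHO11* by 4.92 and PHO84 by 3.86. The spacers rose at 24 h (IGS1-2S 4.41, IGS2-1S 3.36, IGS2-1AS 3.25, IGS1-2AS 2.27) and at 48 h (3.87, 3.05, 2.70 and 3.05 in the same order). Ribosomal proteins fell for 136 members at 48 h (median −1.33, adjusted p = 2.58e-30, adjusted p = 0.133 with an estimated correlation) and ribosome biogenesis for 88 (median −1.49, adjusted p = 1.7e-27, adjusted p = 0.177 with an estimated correlation). General stress response rose for 37 (median 2.55, adjusted p = 1.61e-15, adjusted p = 0.133 with an estimated correlation), phosphate genes fell for 15 and rose for 3 (median −2.33, adjusted p = 2.48e-06, adjusted p = 0.154 with an estimated correlation), and daughter cell markers fell for 11 (median −1.69, adjusted p = 7.73e-06, adjusted p = 0.221 with an estimated correlation). Of 31 lists 19 were called at 48 h, none with an estimated correlation. The plasmid feature 4308..5198 fell by 0.44 at 24 h and 0.49 at 48 h (adjusted p = 0.0102 and 0.00396), but stood at 0.10 and 0.37 after quantile normalization. In all 1752 genes rose and 1717 fell at 24 h, and 2047 rose and 1969 fell at 48 h.

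Across the genes the change of wild type at 48 h had a Pearson correlation of 0.935 with that of mus81 and 0.873 with that of the control strain, but 0.406 with that of the aged wild-type library of the hst3 hst4 table. Genes are not independent replicates, so these correlations describe the profiles only.

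The mus81 strain was compared with wild type to ask whether loss of the Mus81 nuclease altered spacer transcripts or the ageing profile; Mus81 acts with Mms4 on joined DNA molecules during repair. In log phase no spacer feature was called (adjusted p = 0.998; IGS1-2S at 0.68, SE 0.36, and IGS2-1S at 0.66, SE 0.30), although the spacer share of both mus81 libraries lay above that of both wild-type libraries. In all 20 genes were higher and 7 lower (282 at unadjusted p under 0.05; n = 2 per group). NCA3 was higher by 1.97 (SE 0.23), HSP12 by 1.97 (SE 0.19, adjusted p = 4.88e-05) and BNA2 by 1.49. MDH2 was lower at −2.98 (SE 0.21), URA1 at −2.41 (SE 0.16), RIB4 at −1.89 (SE 0.12) and URA4 at −1.41 (SE 0.12). URA3 was higher in mus81 by 7.06. At every age an effect of this marker on other genes could therefore not be told apart from loss of Mus81. In aged hst3 hst4 cells URA1 was also lower than in wild type, at −3, and URA3 higher by 9.02. The split of higher and lower genes differed between alternatives: 5 were higher and 6 lower with voom, 5 and 6 without the lowest 25 percent of genes, 6 and 4 after quantile normalization, 4 and 9 with only these groups and 12 and 4 without the variance trend. The count of 27 fell to 17 without mus81 log replicate 1 and to 13 without mus81 log replicate 2. Of 31 lists 11 were called, none with an estimated correlation; haploid-specific genes had a median of 0.33 (adjusted p = 5.07e-07, adjusted p = 0.0758 with an estimated correlation).

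At 24 h the spacer features IGS2-1AS (−2.50, SE 0.44, adjusted p = 0.022), IGS2-1S (−2.27, SE 0.30, adjusted p = 0.00334) and IGS1-2S (−2.23, SE 0.36, adjusted p = 0.0162) were lower in mus81 than in wild type, and IGS1-2AS at −2.16 was not called (adjusted p = 0.0558; n = 2 per group). URA1 was lower at −2.32 and MDH2 at −2.08, and YLR194C was higher by 1.36 (SE 0.24) and TMA10 by 1.16 (SE 0.20). In all 47 genes were higher and 15 lower. Daughter cell markers were lower for 2 members (9 adjusted over the list alone; median −0.76, adjusted p = 2.53e-09, adjusted p = 0.344 with an estimated correlation), and respiratory chain and TCA genes were higher for 2 (13 adjusted over the list alone; median 0.34, adjusted p = 1.63e-13, adjusted p = 0.344 with an estimated correlation). Ribosomal proteins had a median of −0.14 (adjusted p = 7.71e-05, adjusted p = 0.769 with an estimated correlation), and of 0 with the test turned after quantile normalization. The count of 62 moved with most alternatives. Without the variance trend 2 genes were called and no spacer feature was among them. It was 38 after quantile normalization, 96 without the lowest 25 percent of genes, 126 with title numbers of replicates as blocks and 14 with only the groups compared. It was 748 without wild-type 24 h replicate 1, 6 without wild-type 24 h replicate 2, 35 without wild-type 48 h replicate 1 and 35 without wild-type 48 h replicate 2. It was 24 without mus81 log replicate 1, 18 without mus81 log replicate 2, 8 without mus81 24 h replicate 1 and 4 without mus81 24 h replicate 2.

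At 48 h IGS1-2S (−3.12, SE 0.36, adjusted p = 0.000523), IGS2-1AS (−2.82, SE 0.44, adjusted p = 0.00978) and IGS2-1S (−2.20, SE 0.30, adjusted p = 0.0028) were lower in mus81, while IGS1-2AS at −1.22 was not called (adjusted p = 0.627; n = 2 per group). The 2-micron feature 2271..2816 was lower at −1.14 (SE 0.13, adjusted p = 0.000426), and the plasmid list was lower for 3 of 4 features (4 adjusted over the list alone; median −0.85, adjusted p = 1.6e-13, adjusted p = 0.0433 with an estimated correlation). URA1 was lower at −2.49 (SE 0.16), RIB4 at −1.87 and DSE1 at −1.03, and SSQ1 was higher by 0.67 (SE 0.12). Gluconeogenesis genes were lower for 2 members (3 adjusted over the list alone; median −0.27, adjusted p = 4.64e-05, adjusted p = 0.0433 with an estimated correlation), such as PCK1 at −1.35. The phosphate list had a median of −0.65 with 7 members lower when adjusted over the list alone (adjusted p = 1.73e-12, adjusted p = 0.132 with an estimated correlation); PHO84 at −1.37 and SPL2 at −1.28 did not pass over all genes. In all 2 genes were higher and 14 lower. Without the variance trend 2 genes were called, none of them a spacer or plasmid feature. The count was 31 with voom on the recovered reads, 30 after quantile normalization (4 higher, 26 lower), 30 with title numbers of replicates as blocks and 28 with these numbers crossed. The count of 16 was 27 without wild-type 24 h replicate 1 or wild-type 24 h replicate 2, 8 without wild-type 48 h replicate 2 and 9 without mus81 48 h replicate 2.

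Averaged over the ages, mus81 had 84 genes higher and 43 lower than wild type, with NCA3 higher by 1.05 (SE 0.13), and with MDH2 lower at −2.43 (SE 0.12), URA1 at −2.41 (SE 0.09) and RIB4 at −1.80 (n = 6 per strain). The deleted MUS81 itself stood at −5.27 (SE 0.48) and the marker URA3 at 4.56 (SE 0.43). IGS2-1AS was lower at −1.73 (adjusted p = 0.00322). Daughter cell markers were lower for 7 members (10 adjusted over the list alone; median −0.50, adjusted p = 2.79e-14, adjusted p = 0.152 with an estimated correlation). Without the variance trend 1 gene was higher and 5 lower, and with voom 80 and 51. The count of 127 was 81 without wild-type log replicate 2, 335 without wild-type 24 h replicate 1 and 36 without wild-type 48 h replicate 2. It was 41 and 48 without mus81 log replicate 1 and replicate 2, 57 and 82 without mus81 24 h replicate 1 and replicate 2, and 60 without mus81 48 h replicate 2.

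The difference of the age change between the strains was tested as an interaction. From log phase to 48 h IGS1-2S rose less in mus81 by −3.81 (SE 0.51, adjusted p = 0.00634) and IGS2-1S by −2.86 (SE 0.42, adjusted p = 0.0129). The antisense spacer features were not called, with IGS2-1AS at −2.97 (SE 0.63, adjusted p = 0.173) and IGS1-2AS at −1.31 (SE 0.72, adjusted p = 0.998). HSP12 rose less by −1.96 (SE 0.27, adjusted p = 0.00634) and 2271..2816 by −1.16 (SE 0.18, adjusted p = 0.015). The value of HSP12 mirrors its log-phase level, which was higher in mus81 by 1.97, and does not show a lower level at 48 h. The count was 8 genes (332 at unadjusted p under 0.05, and 3 with voom). To 24 h only IGS2-1S was called, at −2.93 (SE 0.42, adjusted p = 0.0389), with 380 genes at unadjusted p under 0.05. The other spacer features were IGS1-2S at −2.92 (adjusted p = 0.0999), IGS2-1AS at −2.64 (adjusted p = 0.374) and IGS1-2AS at −2.26 (adjusted p = 0.72). After quantile normalization the limma count was 0 for both ages, and without the variance trend it was 2 to 48 h and 0 to 24 h. With only the groups compared it was 13 to 48 h and 0 to 24 h. The 24 h count was also 0 with title numbers of replicates as blocks, and 2 with the description label as a block. The 48 h count of 8 was 5 without wild-type log replicate 1, 3 without wild-type 48 h replicate 1, 0 without wild-type 48 h replicate 2, 5 without mus81 log replicate 2 and 0 without mus81 48 h replicate 2. The 24 h count of 1 was 42 without wild-type 24 h replicate 1 and 2 without mus81 24 h replicate 1. It was 0 without any of wild-type log replicate 1, wild-type 24 h replicate 2, wild-type 48 h replicate 1, wild-type 48 h replicate 2, mus81 log replicate 1 and mus81 24 h replicate 2.

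Chromosome XII right of the rDNA (334 genes, 490406 to 1077898) was tested as a region, because it lies between the rDNA array and the telomere. In wild type 185 of its genes rose and 57 fell at 48 h (191 and 60 adjusted over the list alone; median 0.77, adjusted p = 3.68e-05, adjusted p = 0.184 with an estimated correlation), among them TMA10 at 7.83 and CDA1 at 7.29. At 24 h 126 rose and 54 fell (median 0.36, adjusted p = 0.00408, adjusted p = 0.365 with an estimated correlation), and between 24 h and 48 h 88 rose and 17 fell (median 0.33, adjusted p = 1.11e-07, adjusted p = 0.131 with an estimated correlation). In mus81 210 rose and 25 fell at 24 h (median 0.79, adjusted p = 1.03e-12, adjusted p = 0.0984 with an estimated correlation), and 213 rose and 38 fell at 48 h (median 0.93, adjusted p = 2.55e-10, adjusted p = 0.122 with an estimated correlation). Among 33 chromosome arms the region had the highest median in mus81 at both ages (highest other 0.45 at 24 h and 0.69 at 48 h), but in wild type other arms reached 0.65 at 24 h and 0.81 at 48 h.

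The region was higher in mus81 than in wild type at 24 h, for 40 genes against 1 lower (174 and 2 adjusted over the list alone), with a median of 0.46 (adjusted p = 6.97e-42, adjusted p = 0.0228 with an estimated correlation; n = 2 per group). At 48 h 1 gene was higher and 1 lower (27 and 2 adjusted over the list alone; median 0.27, adjusted p = 8.94e-28, adjusted p = 0.0433 with an estimated correlation). In log phase the median was 0.01 (adjusted p = 0.581). Over 4 parts of the region in order from the rDNA the median at 24 h was 0.46, 0.54, 0.44 and 0.43, and at 48 h 0.29, 0.24, 0.27 and 0.26. Across 20 alternatives the median at 24 h stayed between 0.40 and 0.55, and it was 0.44 without wild-type 24 h replicate 2 (adjusted p = 6.46e-43). The interaction gave 0.41 to 24 h (adjusted p = 1.42e-41, adjusted p = 0.0233 with an estimated correlation) and 0.23 to 48 h (adjusted p = 5.89e-15, adjusted p = 0.0741 with an estimated correlation). No other arm had a median above 0.05 at 24 h or 0.03 at 48 h. Other lists differed between the same libraries: at 24 h daughter cell markers had a median of −0.76 in mus81 against wild type (adjusted p = 2.53e-09, adjusted p = 0.344 with an estimated correlation), and at 48 h −0.59 (adjusted p = 9.46e-13, adjusted p = 0.151 with an estimated correlation). The median percentile of the general stress list at 24 h was 65.3 and 56.6 in wild type and 72.7 and 69.5 in mus81.

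**Figure D2:**
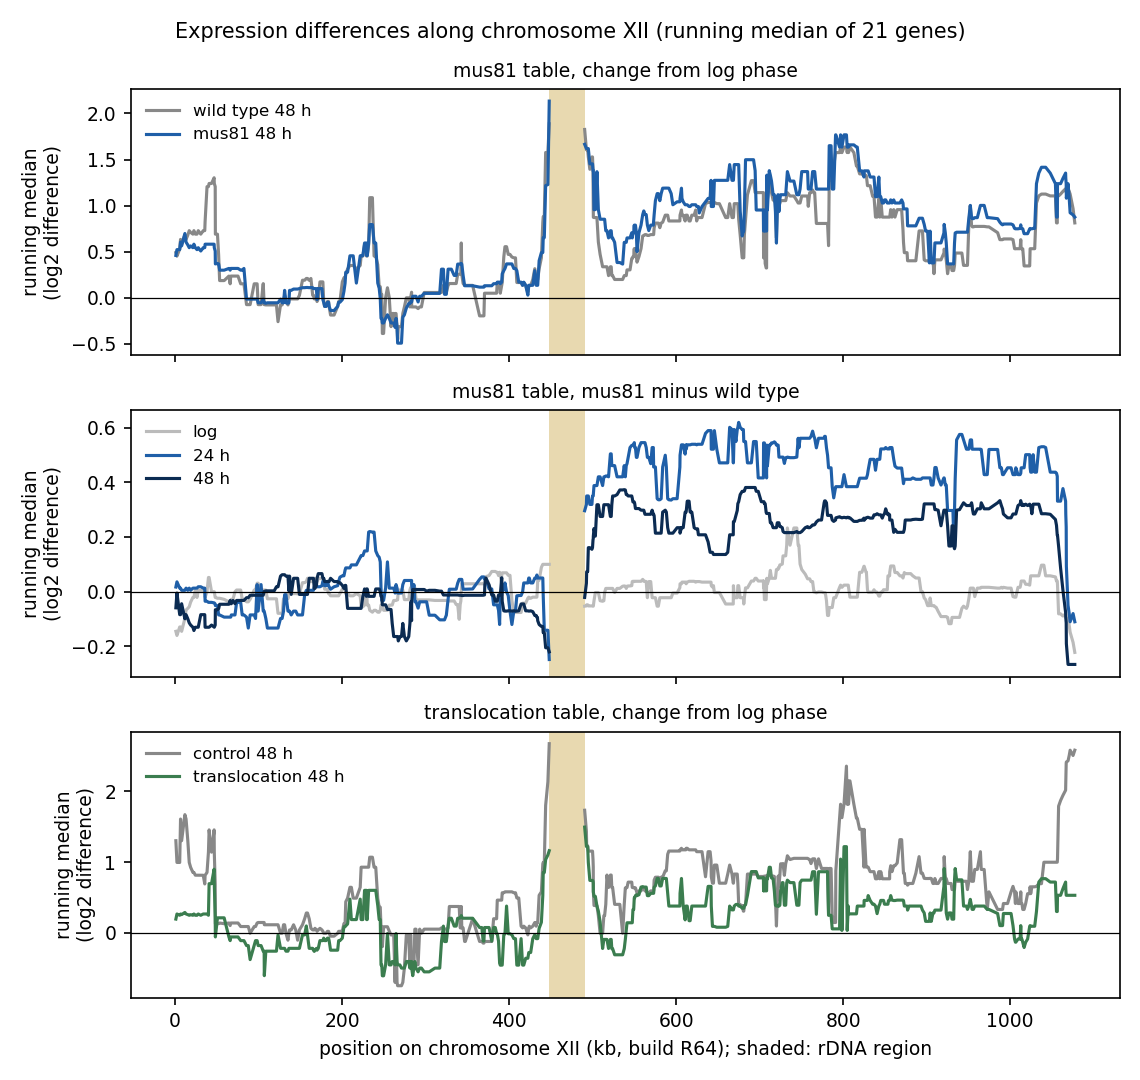
Running median over 21 genes of log2 differences along chromosome XII: the 48 h change in wild type and mus81, the difference between these strains at each age, and the 48 h change in control and translocation strains. The rDNA region is shaded.

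The hst3 hst4 strain was aged to ask how cells lacking both histone H3 lysine 56 deacetylases change. HUG1 rose by 4.16 (SE 0.21, adjusted p = 0.00114), PIR3 by 3.63 (SE 0.10, adjusted p = 0.00104), NCA3 by 3.67 (SE 0.15) and RNR3 by 3.19 (SE 0.30, adjusted p = 0.00181), and HSP30 fell by 4.06 (SE 0.44, adjusted p = 0.0023), YHB1 by 2.97 and HTB2 by 2.70 (n = 2 per group). IGS2-1AS rose 2.83-fold (log2 SE 0.17, adjusted p = 0.0025) and IGS1-2AS 2.83-fold (log2 SE 0.41, adjusted p = 0.0293). In all 1894 genes rose and 1558 fell. This total of 3452 fell to 1433 without hst3 hst4 aged replicate 1 and to 1389 without hst3 hst4 aged replicate 2.

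Of 30 lists 22 were called in aged hst3 hst4 cells, none with an estimated correlation. Ribosomal proteins fell for 130 of 138 members (132 adjusted over the list alone; median −1.31, adjusted p = 3.95e-33, adjusted p = 0.321 with an estimated correlation), such as RPL9A at −2.22. The age change had a Spearman correlation of 0.35 with gene length across genes, and less the genes of like length the median of the ribosomal proteins was −1.21. The proteasome fell for 23 of 34 (24 adjusted over the list alone; median −0.51, adjusted p = 1.04e-05, adjusted p = 0.282 with an estimated correlation). Gluconeogenesis genes rose for 22 of 26 and fell for 1 (median 2.22, adjusted p = 1.89e-07, adjusted p = 0.282 with an estimated correlation), with POT1 at 4.08 and FBP1 at 4.02. DNA damage response genes rose for 16 of 25 (median 0.73, adjusted p = 0.00058, adjusted p = 0.321 with an estimated correlation). Histones fell for 9 of 11 (median −1.25, adjusted p = 5.15e-05, adjusted p = 0.282 with an estimated correlation). General stress response rose for 18 and fell for 6 of 40 (median 0.39, adjusted p = 0.0582). Heat shock chaperones rose for 3 and fell for 8 of 25 (median −0.55, against −0.05 with the test turned after quantile normalization; adjusted p = 0.0495, adjusted p = 0.519 with an estimated correlation). Chromosome XII right of the rDNA rose for 200 of 333 genes and fell for 25 (median 0.79, adjusted p = 6.15e-09, adjusted p = 0.282 with an estimated correlation), and chromosome XII left rose for 90 of 228 and fell for 32 (median 0.42, adjusted p = 0.0117, adjusted p = 0.321 with an estimated correlation).

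The hst3 hst4 strain was compared with wild type at each age to ask whether its spacers and damage genes already differed in young cells. In log phase IGS1-2AS was higher by 5.70 (SE 0.50, adjusted p = 0.00787), IGS2-1AS by 4.66 (SE 0.21, adjusted p = 0.00245) and HUG1 by 4.83 (SE 0.26, adjusted p = 0.00282; n = 2 against 1). Aged, HUG1 was higher by 5.35 (SE 0.26, adjusted p = 0.00543), RNR3 by 2.46 and RNR4 by 2.40, while IGS2-1AS at −0.70 (adjusted p = 0.0799) and IGS1-2AS at 0.51 (adjusted p = 0.519) were not called. The age change of the spacers differed between strains, by −5.36 (SE 0.29, adjusted p = 0.0165) for IGS2-1AS and −5.19 (SE 0.70, adjusted p = 0.0361) for IGS1-2AS. Without the variance trend limma called 0 genes for this difference, neither spacer among them (1948 at unadjusted p under 0.05 in that fit), and voom on the recovered reads called 890. In log phase general stress response was lower for 24 of 40 and higher for 1 (median −1.29, adjusted p = 1.76e-10, adjusted p = 0.383 with an estimated correlation). The median percentile of this list within the lone wild-type log library was 86.9, against 25.6 to 29.3 in the 4 log libraries of wild type, control and translocation strain of the other tables. In log phase ribosome biogenesis was higher for 40 (median 0.51, adjusted p = 1.27e-10, adjusted p = 0.396 with an estimated correlation), and ribosomal proteins had a median of 0.00 (adjusted p = 0.673; 0.17 after quantile normalization). The difference between the strains had a Spearman correlation with gene length across genes of −0.20 in log phase and 0.34 aged. Aged, ribosomal proteins were lower for 125 (median −1.02, −0.97 less the genes of like length, adjusted p = 7.35e-43, adjusted p = 0.353 with an estimated correlation) and meiosis genes higher for 29 (median 1.20, adjusted p = 1.35e-13, adjusted p = 0.208 with an estimated correlation). Chromosome XII right had a median of 0.28 in aged cells (41 higher, 16 lower; adjusted p = 0.000722, adjusted p = 0.373 with an estimated correlation) and −0.03 in log phase (adjusted p = 0.531).

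In log phase 577 genes were higher and 553 lower in hst3 hst4 than in wild type, aged 558 and 561, and the age change differed for 284 and 399. These counts rest on 2 residual degrees of freedom and on lone wild-type libraries. The wild-type libraries and hst3 hst4 replicate 1 of each age shared a lane, and hst3 hst4 replicate 2 of each age came from another. The spread between replicates therefore includes a difference between lanes. Only the wild-type libraries were labelled with a batch, so a batch effect could not be told apart from strain. Without the variance trend 383 genes were called in log phase and 620 aged, and with only the groups compared 142 and 3703. The log count of 1130 was 3928 and 3360 without hst3 hst4 log replicate 1 and replicate 2, and 195 without hst3 hst4 aged replicate 1 or hst3 hst4 aged replicate 2. The aged count of 1119 was 3713 and 3681 without hst3 hst4 log replicate 1 and replicate 2, and 4 and 6 without hst3 hst4 aged replicate 1 and replicate 2. The count of 683 for the difference in age change was 3845 and 3399 without hst3 hst4 log replicate 1 and replicate 2, and 0 without hst3 hst4 aged replicate 1 or hst3 hst4 aged replicate 2.

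The aged wild-type library of this table was set against its log library without a test (n = 1 each). IGS2-1AS was higher by 6.86, IGS1-2AS by 6.69 and HUG1 by 3.64, and RGI1 was lower at −3.19 and BTN2 at −2.91. The general stress list had a median of −1.06 and heat shock chaperones of −1.10, both at percentile 0.0 of 10000 matched random lists, and gluconeogenesis had 0.77 at percentile 100. Chromosome XII right of the rDNA had a median of 0.32 at percentile 100.

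The translocation strain was compared with its control to ask whether the age change of the chromosome XII genes followed their place beside the rDNA. The control had a median of 0.52 over chromosome XII right of the rDNA at 24 h against log phase and 0.79 at 48 h, both at percentile 100 of 10000 matched random lists (n = 1 each). The translocation strain had 0.17 at 24 h (percentile 61.36) and 0.39 at 48 h (percentile 100). Less the genes of like length, a check chosen after the data had been seen, the control had 0.26 and 0.61 and the translocation strain 0.00 and 0.27. Set directly against the control, the region stood at −0.11 in log phase (percentile 91.64), −0.22 at 24 h and −0.25 at 48 h (percentile 0.0 at both ages; at 48 h 70 genes were higher and 264 lower). At 48 h the 4 parts of the region from the rDNA outward had medians of −0.24, −0.25, −0.25 and −0.25. No other arm lay below −0.14 at 24 h or −0.19 at 48 h. Chromosome XII left had −0.10 (percentile 0.34) at 24 h and −0.14 (percentile 0.0) at 48 h. Chromosome V left had 0.16 (percentile 99.9) and 0.00 (percentile 47.16), and chromosome V right 0.02 (percentile 76.02) and 0.03 (percentile 89.66).

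**Figure D3:**
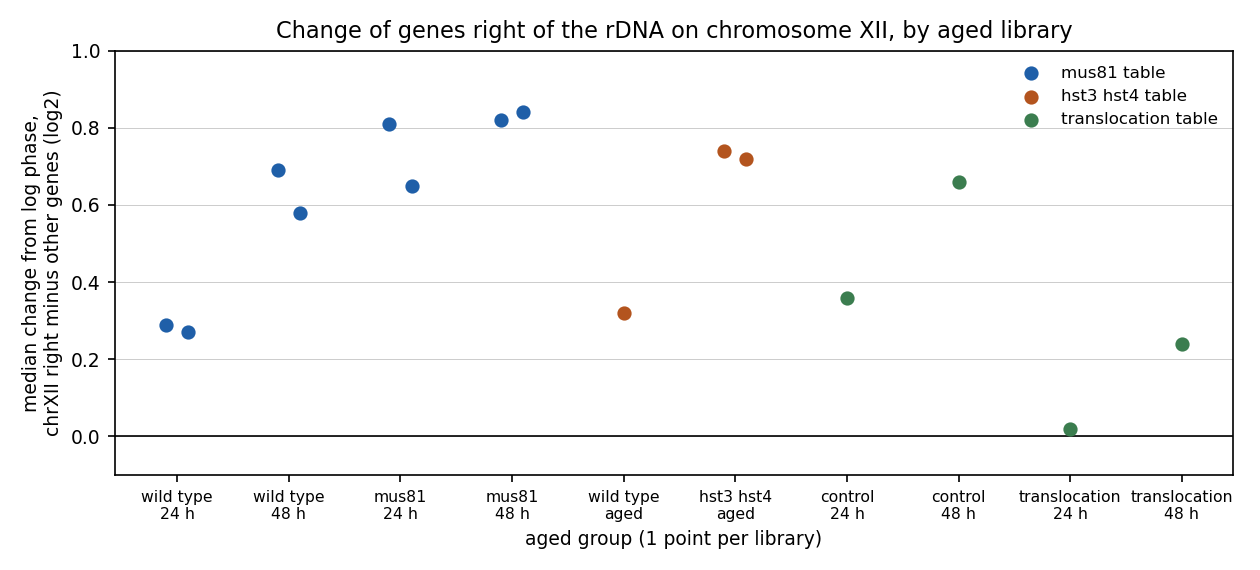
Median log2 change over chromosome XII right of the rDNA less that of the other genes, for each aged library against the log libraries of its strain. Tables were normalised separately.

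With strain and age as additive terms over the 6 libraries, 1 gene was called between translocation strain and control: YNL143C, higher by 3.54 (SE 0.31, adjusted p = 0.024; 78 genes at unadjusted p under 0.05; n = 3 per strain). YNL143C also differed between replicates elsewhere, with 133 and 1627 reads in wild type at 48 h and 219 and 7 reads in hst3 hst4 in log phase. Without the variance trend limma called 0 genes (161 at unadjusted p under 0.05), and voom on the recovered reads called 1. Chromosome XII right of the rDNA was lower by a median of −0.14 (adjusted p = 1.51e-08, adjusted p = 0.994 with an estimated correlation), with no gene of the region called. The rDNA locus coding list had −0.53 (adjusted p = 0.000977, adjusted p = 0.994 with an estimated correlation) and G2/M genes 0.09 (adjusted p = 0.0246, adjusted p = 0.994 with an estimated correlation). The count of 1 was 152 without the control 24 h library and 160 without the translocation 24 h library. With 1 library left out the median of chromosome XII right ranged from −0.24 to −0.11, and its call did not hold for 4 of the 6 libraries. Nor was the region called with both 24 h libraries left out (−0.16, adjusted p = 0.0768 by camera). In log phase the difference between these strains was larger for longer genes (Spearman correlation 0.62 across genes, which are not independent replicates), with medians of 0.61 over 445 genes longer than 3 kb and −0.31 over 1082 genes shorter than 1 kb; this was examined after the data had been seen. Less the genes of like length, chromosome XII right stood at 0.01 in log phase, −0.20 at 24 h and −0.27 at 48 h.

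To ask what age did in both strains of this table, the age terms of the additive model were read: HSP12 rose by 8.03 (SE 0.25), HSP26 by 7.46 and PIR3 by 7.42 at 48 h, while PHO12* fell by 4.31 and YHB1 by 3.49 (n = 2 per age). General stress response rose for 36 of 40 (median 2.84, adjusted p = 1.28e-16), ribosome biogenesis fell for 85 (median −1.58, adjusted p = 1.05e-31) and ribosomal proteins fell for 109 (median −1.04, adjusted p = 6.33e-23, adjusted p = 0.381 with an estimated correlation). None of the 19 lists called at 48 h was called with an estimated correlation, where the lowest adjusted p was 0.292. In all 1538 genes rose and 1146 fell at 48 h, and 1406 rose and 729 fell at 24 h. At 24 h 632 rose and 668 fell without the lowest 25 percent of genes, and 675 and 547 after quantile normalization. The 48 h count of 2684 fell to 631 without the control 48 h library and to 1075 without the translocation 48 h library, and the 24 h count of 2135 to 1396 and 1410 without these libraries.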

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

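The tests on chromosome XII given in this part were chosen after the result was seen; those on the stress genes and on other splits were written down before they were run.

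Age changes that differed between strains were listed because a difference between groups can come from the groups or from single libraries. Between mus81 and wild type the change to 24 h differed for 1 gene and 8 lists, with IGS2-1S at −2.93 and chromosome XII right of the rDNA at 0.41; this region alone was still called with an estimated correlation (adjusted p = 0.0233). The change to 48 h differed for 8 genes and 19 lists: IGS1-2S at −3.81, IGS2-1S at −2.86, HSP12 at −1.96, the plasmid feature 2271..2816 at −1.16, general stress response at −0.36 and chromosome XII right of the rDNA at 0.23. HSP12 was already higher in mus81 by 1.97 in log phase. None of these 19 lists was called with an estimated correlation (lowest adjusted p = 0.0705), and after quantile normalization no gene was called for either age. The 24 h call was also lost without the variance trend, with title numbers of replicates as blocks and with only the groups compared. Between hst3 hst4 and wild type 683 genes and 18 lists differed, against lone wild-type libraries, and none of these lists was called with an estimated correlation (lowest adjusted p = 0.382). Higher there were IGD1 at 3.23, MTH1 at 3.13, CTT1 at 2.98, YCL042W at 2.93, SDS24 at 2.85, general stress response at 1.28 and chromosome XII right of the rDNA at 0.35. Lower were IGS2-1AS at −5.36, IGS1-2AS at −5.19, FIT2 at −3.84, PHO84 at −3.29 and SPL2 at −3.21. The general stress list stood at −1.06 in the aged wild-type library of the hst3 hst4 table, opposite to wild type of the mus81 table; this was not tested across tables.

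For the low stress genes of that aged library, the median percentile of the stress list within its log library was 86.9, against 25.6 to 29.3 in the 4 log libraries of wild type, control and translocation strain in the other tables. In the aged library it was 73.8, inside the range of 56.6 to 81.9 of the 6 aged wild-type and control libraries there. After quantile normalization the change remained at −0.88, so the deposited scaling was excluded. A high level in the log library may therefore account for the sign. The hst3 hst4 log libraries stood at 66.0 and 74.3, also above those of the other tables, so every contrast with a log library of this table could carry it, hst3 hst4 aged against log included.

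The rise of chromosome XII right of the rDNA in wild type at 48 h was weighed against its composition. Without subtelomeric genes and near-identical copies the median was 0.74 over 308 genes. In the part of the region farthest from the rDNA it was 0.64 (SE 0.13), against 0.11 for other genes. The highest median of 10000 random lists matched on expression was 0.32, but such lists draw genes from the whole genome. The highest other chromosome arm had a median of 0.81, so a rise of this size was not particular to the region. Less the genes of like length the median was 0.6, and camera with an estimated correlation did not call it (adjusted p = 0.184). Ends, copies and nearness to the rDNA do not account for the rise, and neither does expression level taken gene by gene. A direct effect of age remains possible and was not tested.

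For mus81 against wild type averaged over the ages, the real grouping gave 127 genes and the highest of the other splits gave 62. The real grouping ranked 1 among 100 splits. Every other split had both strains on each side, which weakens known strain differences such as the deleted MUS81 and lowers its count. The rank therefore cannot exclude an accidental division as the source of the other called genes. For the translocation strain the real grouping gave 1 gene and another split gave 277; the 10 splits, of which 3 reached the real value, are too few for this test. The splits with 277 genes kept both libraries of 24 h together and both of 48 h together, so with age in the model they rested on the difference between the strains in log phase.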

How the results depend on the processing

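Voom on recovered reads, the crossed pairing and the translocation libraries left out were added after the data were seen; the other alternatives were chosen before. The cause of a moved value was not tested unless stated.

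Median centring and no filter kept all 18 counts within 1.5-fold. Quantile normalization moved 6 of 18 counts: mus81 against wild type to 10 (6 higher, 4 lower) in log phase, 38 (29 and 9) at 24 h and 30 (4 and 26) at 48 h, both interactions with age to 0 and 0, and 24 h against log in the translocation table to 1222 (675 and 547). The share of higher genes among those called went from 74.1 to 60 percent for mus81 against wild type in log phase, from 54.9 to 43.7 for hst3 hst4 aged against log and from 65.9 to 55.2 for 24 h in the translocation table. Leaving out the lowest 25 percent of genes moved 4 counts: mus81 against wild type to 11 (5 and 6) in log phase and 96 (73 and 23) at 24 h, the 48 h interaction to 4, and translocation 24 h against log to 1300 (632 and 668).

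Without a trend 11 of 18 counts moved. Wild type 48 h against 24 h went to 950, mus81 against wild type to 16, 2 and 2 in log phase, at 24 h and at 48 h, the interactions to 0 and 2, and the average over ages to 6 (1 and 5). hst3 hst4 against wild type went to 383 in log phase and 620 aged, its interaction to 0, and translocation strain against control to 0. Voom moved 3 of 18: mus81 against wild type to 11 (5 and 6) in log phase and 31 at 48 h, and the 48 h interaction to 3. With only the groups compared 7 of 13 moved: wild type 48 h against 24 h to 945, mus81 against wild type to 13 (4 and 9) in log phase and 14 at 24 h, the interactions to 0 and 13, and hst3 hst4 against wild type to 142 in log phase and 3703 aged.

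Title numbers as a replicate block gave 126 at 24 h and 30 at 48 h for mus81 against wild type and 0 for the 24 h interaction. The description label as a block gave 2 for the latter, and crossed numbers gave 28 at 48 h. The numbers were not taken as pairs, because the labels do not say that a number or description label marks a shared batch or day. The description labels cross the title numbers at 24 h in both strains of the mus81 table. Not every pair of groups deviated together by title number, and this check was made by title number only. Correlations of the deviations from group means ranged from −0.23 to 0.29 in the mus81 table, with 7 pairs of groups over 0.1, among them all pairs of mus81 groups (0.15, 0.20 and 0.21); in hst3 hst4 the value was 0.02.

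Leaving out 1 library moved 57 counts and kept 113. Lowest and highest counts were 2484 and 3277 for wild type at 24 h, 3590 and 4420 at 48 h, 283 and 1968 for 48 h against 24 h, 2768 and 3716 for mus81 at 24 h and 3370 and 4285 at 48 h. For mus81 against wild type they were 13 and 40 in log phase, 4 and 748 at 24 h, 8 and 27 at 48 h, 36 and 335 averaged, and 0 and 42 and 0 and 11 for the interactions. For hst3 hst4 they were 1389 and 4803 aged against log, 195 and 3928 against wild type in log phase, 4 and 3713 aged, and 0 and 3845 for the interaction. In the translocation table they were 1 and 160 for strain, 1396 and 2511 at 24 h and 631 and 3302 at 48 h. The chromosome XII right median ranged from −0.24 to −0.11 for strain (highest adjusted p = 0.127), from 0.17 to 0.52 at 24 h and from 0.46 to 0.79 at 48 h (highest adjusted p = 0.115). With both 24 h libraries left out, strain gave 157 genes (151 higher, 6 lower) and −0.16 for the region (adjusted p = 0.0768).

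Over 554 list tests, called or not, an estimated correlation weakened 283 calls. For chromosome XII right of the rDNA it did so for wild type at 24 h (0.36, adjusted p = 0.365), 48 h (0.77, 0.184) and 48 h against 24 h (0.33, 0.131), mus81 at 24 h (0.79, 0.0984) and 48 h (0.93, 0.122), the 48 h interaction (0.23, 0.0741), hst3 hst4 aged against log (0.79, 0.282), against wild type aged (0.28, 0.373) and its interaction (0.35, 0.448), translocation strain (−0.14, 0.994) and translocation 48 h (0.65, 0.453). With an estimated correlation the region stayed called between mus81 and wild type at 24 h, at 48 h, averaged over ages and in the 24 h interaction. The only other calls left were the plasmid and gluconeogenesis lists at 48 h between these strains. Ranks left 533 of the 554 list tests the same, called or not, and made 13 stronger and 8 weaker. The region without its end and copies had the same outcome in all 18 comparisons, called or not.

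Quantile normalization turned the direction of the following. Ergosterol: wild type 24 h (0.07) and 48 h (0.07), mus81 24 h (0.06), translocation 24 h (−0.11) and 48 h (−0.02). Proteasome: wild type 24 h (0.17), 48 h (0.31) and 48 h against 24 h (0.15), mus81 24 h (0.20) and 48 h (0.33), hst3 hst4 against wild type aged (0.02). Amino acid biosynthesis: wild type 48 h (0.10), mus81 24 h (0.18), translocation 48 h (0.24). Ribosomal proteins: mus81 against wild type at 24 h (0), hst3 hst4 against wild type in log phase (0.17), translocation 24 h (−0.01). It also turned heat shock chaperones in hst3 hst4 aged against log (−0.05) and the plasmid feature 4308..5198 in mus81 at 24 h (0.10) and 48 h (0.37). Leaving out the lowest 25 percent turned haploid-specific genes in the 48 h interaction (−0.06), meiosis genes in hst3 hst4 against wild type in log phase (−0.30) and hexose transporters aged (−0.38).

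A mean in place of a median turned chromosome XII left in the translocation strain at 48 h (0.20) and, against control in log phase, chromosome XII left (0.14), rDNA locus coding (0.13) and gluconeogenesis (0.04). Leaving out 1 library turned amino acid genes in mus81 against wild type at 24 h (from −0.18 without wild-type 24 h replicate 2 to 0.02 without replicate 1) and ribosome biogenesis in the 24 h interaction (from −0.36 without wild-type 24 h replicate 1 to 0.05 without replicate 2). For the strain term it turned ribosomal proteins (from −0.17 without the control 24 h library to 0.08) and proteasome (from −0.09 without the control 24 h library to 0.10), the highest being without either log library.

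Leaving out the hst3 hst4 libraries of the other lane left 0 residual degrees of freedom and was not run. Apart from voom, the planned count tools were not run, and pseudocounts were not varied, because the unit was log2. The depth of 1656535 reads in wild-type 24 h replicate 2 limits what can be said of weakly expressed genes at 24 h.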

Other observations

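Of the tests given in this part, those of depth and of library name were chosen after the URA3 reads were seen, and the condition for mixing was written down before that test was run.

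URA3 had 35 reads in wild-type 24 h replicate 2 (21.1 CPM, reads scaled to depth) and 14 in replicate 1 (2.53 CPM), against 2 and 4 in the wild-type log libraries, 20 and 6 at 48 h (6.62 and 1.51 CPM), 0 in log phase and 3 to 14 aged in the translocation table, and 46.5 to 54.7 CPM in mus81 libraries. At the depth of replicate 2 only 4.2 reads would follow from replicate 1 (exact binomial p = 9.87e-13), but this p covers counting error only and compares single libraries, so shallow sequencing was not excluded. MUS81 stood at 23.5 CPM there and at 0 to 2.47 in mus81 libraries, so a mus81 library under a wild-type name was excluded. Partial mixing with mus81 material remains possible but undecided: over 23 genes the median place of the library between wild type (0) and mus81 (1) was 0.01, with an interval from −0.8 to 0.23. Of these genes 10 lay below 0, among them NCA3 at −0.84, STE3 at −6.24 and AMS1 at −4.55. The last of these, like STE3, barely differed between the strains at 24 h, so such places say little about mixing. Over the 13 genes more than 0.5 log2 apart between the strains the median was 0.18 with 10 towards mus81. MDH2, RIB4 and MUS81, left out as already seen, lay at 0.41, 0.27 and 0.11. Genotyping reads of URA3 and MUS81 junctions in the raw data would decide whether material was mixed.

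Values in no comparison were also recorded. In hst3 hst4 log replicate 1 against replicate 2 the difference had a Spearman correlation of 0.35 with gene length across genes, in hst3 hst4 aged against log one of 0.35, and in hst3 hst4 against wild type 0.34 aged and −0.20 in log phase; in the mus81 table such values lay between −0.21 and 0.10. The largest higher genes of the translocation strain against control in log phase were long: SNF2 at 3.35 (1154 against 103 reads), MYO5 at 3.27, SEC16 at 3.21, PAN1 at 2.98 and SPT5 at 2.90. LYS2 had 0 reads in both log libraries of the translocation table and 10, 6, 26 and 1 in the aged ones. The length trend was not traced to a cause; RNA integrity values or coverage along genes would test degradation or fragment selection.

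Hypotheses follow from the measured values. That chromosome XII right of the rDNA gains copies in old cells would be tested by DNA sequencing of the same mothers. Its wild-type median without subtelomeric genes and copies was 0.74. The translocated region differed from control by −0.25 at 48 h (n = 1 each), where another arm lay at −0.19. Over the 3 ages camera with an estimated correlation did not call the region between these strains (adjusted p = 0.994). That spacer transcripts and this region are separable would be tested with a strain that forms few circles. In mus81 the sense feature IGS1-2S changed less by −3.81 to 48 h (not called after quantile normalization). The antisense spacer features were not called for this difference. The region changed more by 0.23 (adjusted p = 0.0741 by camera with an estimated correlation).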
